A study of Mus musculus with 6 samples.

How the data were processed

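Small RNA was sequenced from whole heart tissue of 6 male wild-type mice, 8 weeks after surgery. Transverse aortic constriction (TAC) narrows the aorta with a suture and puts a lasting pressure load on the left ventricle. Sham mice undergo the operation without the constriction. Per the labels, 3 mice had sham surgery and 3 had TAC, and each mouse gave 1 library. Mice are named by group and by the animal number in the labels, which is not shared between the groups, so nothing pairs the samples. No batch is given in the sources used here.

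The authors deposited 1 table of whole-number read counts per mature miRNA, with the genomic place or places of each miRNA and 1 column per mouse. Build mm10, HISAT2, StringTie and DESeq2 are named in the submitters' processing notes, with no role or version. RNA was extracted with a kit from Vazyme and libraries were made by a company, per the sample protocols. The counter, the library kit, the adapter trimming and the strand setting are not given in the sources used here. All 6 columns of values were matched to a mouse, and 0 columns were left over. The table had 1966 rows and no repeated name, and 1100 rows had at least 1 count in any library. Total counts ranged from 1226187 to 3509001 per library. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to between 0.855 and 2.45 CPM, for counting error only.

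How the table was made could affect the values in 3 ways, each checked on the table itself. Reads that align to several places were counted at each of them: miR-199a-3p, which has 2 places, held 2.00 times the count of miR-199b-3p, whose mature sequence is identical, in every library. Near-identical miRNAs can therefore share reads. Count ratios hardly varied between libraries for miR-378a-3p and miR-378c, miR-99a-5p and miR-100-5p, miR-27b-3p and miR-27a-3p, and miR-101a-3p and miR-101b-3p. The same held for miR-133a-3p and miR-133b-3p and for let-7c-5p and let-7a-5p. Rows of these pairs are not independent measurements. Other let-7 pairs were not checked, and let-7f-5p did not follow let-7a-5p (log2 changes of 0.30 and -0.36 in TAC relative to sham). Totals count reads with several places more than once. Rows that overlap a row on the opposite strand by 10 nt or more were mostly at 0: 82 of the 90 rows overlapped at every place, against 784 of 1873 rows with no overlap. A count of 0 in such a row was not read as absence.

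Coordinates are those of the table, 1-based. The annotation of each place came from GENCODE mouse release M21, which uses the same assembly. Mature sequences, printed as DNA, were taken from the hairpin transcripts of that release at the coordinates of the table, and were found for 1907 rows.

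The main test was edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr, no covariate) on the counts of all 6 libraries, run in R 4.3.3 with Benjamini-Hochberg adjustment. miRNAs with an adjusted p under 0.05 are called higher or lower, in TAC relative to sham. CPM values are TMM-scaled. Levels are given as mean ± SD and log2 fold changes with ± their standard error, with 3 mice per group throughout. The 20 miRNA lists were tested with camera from limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 17 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Shares of counts were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3. They are shares of each library's total counts, without TMM scaling, so a share and a log2 fold change are on different levels.

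The following were fixed before the data were examined: the test, the lists, the alternative analyses and the rule for named miRNAs. The rule took the 12 largest changes in each direction among called miRNAs with a mean of at least 10 CPM, the 5 most abundant miRNAs, a panel of 25 known from heart and blood, and up to 4 called members of each list with the smallest p. miRNAs named outside it are marked as chosen after their values were seen.

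Alternative analyses fixed at that time were DESeq2 1.42.0, limma-voom, robust quasi-likelihood, 4 other scalings (RLE size factors, library totals, upper quartile, totals without the 5 most abundant miRNAs), 2 other low-count filters and leaving out each mouse in turn. Summing rows of a repeated name was not run, because no name repeats. The following were added after the data were seen: 1 row per group of near-identical sequences (up to 2 mismatches), counts divided by the number of places, libraries thinned to the smallest total, removal of rows that overlap an opposite-strand row, and a trend with GC content taken from each library by local regression (span 0.75). Correlations used scipy 1.17.1 with 100000 permutations.

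The pipeline was tested on simulated data: in 20 simulations of TAC against sham on the 1966 rows, with 200 miRNAs changed in each, edgeR called 25.7% of tested miRNAs changed by 1.5-fold, 71.2% of those changed by 2-fold and 98.4% of those changed by 4-fold. Of all calls, 4.17% were false. A list moved by 1.5-fold was called in 20 of 20 simulations and unmoved lists in 3 of 300 tests. The simulated miRNAs were drawn independently of each other. The list result therefore does not cover lists with correlated members, such as that of miR-199 and miR-214 (estimated correlation 0.83). Changes were drawn up or down at random, at the TMM-scaled depths. The 4.17% therefore does not cover errors from the scaling or from rows that share reads.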

Results

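Mature miRNAs were counted in hearts of 3 sham-operated mice (animals 47, 68 and 69) and 3 mice with TAC (animals 29, 78 and 81), 8 weeks after surgery. Total counts were 3509001, 1818725 and 2263006 in sham and 1795831, 1640109 and 1226187 in TAC, in that order of animals. No pair of libraries of a group was a copy of one library (chi-square per degree of freedom of 31.6 to 67.8, against counting error only), and each library is its own mouse per the labels. miR-1a-3p, the most abundant miRNA of heart muscle, held 13.9% ± 1.47 of counts in sham and 20.3% ± 1.54 in TAC (SD, n = 3 each). The exact permutation p of that difference of 6.41 percentage points, or 4.22 with counts divided by places, was 0.1, the smallest that 3 against 3 allows. The first principal component took 56.8% of the variance and placed the sham libraries on one side and the TAC libraries on the other.

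The comparison of TAC with sham asks which cardiac miRNAs change under chronic pressure overload. Of 10 tested muscle miRNAs, 8 rose in the hearts labelled TAC. miR-499-5p, encoded in a myosin heavy chain gene, went from 2621 ± 118 to 4814 ± 189 CPM. miR-133a-5p went from 737 ± 151 to 1419 ± 274 CPM (SD, n = 3 each). Of 10 tested members of the miR-30 family 8 rose, with miR-30a-3p at 1426 ± 4.85 CPM in sham and 2414 ± 42.1 in TAC. The 2 lists were called by camera, but had adjusted p = 0.305 and 0.206 with an estimated correlation. miR-21a-5p, known for its rise in cardiac fibroblasts of stressed hearts, fell from 14060 ± 2104 to 6323 ± 1125 CPM. The mesenchymal miR-214-3p fell from 587 ± 111 to 196 ± 29.5 CPM, and a neighbouring pair on chromosome 2, miR-296-3p and miR-298-5p, fell the furthest, 4.50-fold and 4.44-fold. miR-150-5p of lymphocytes and miR-451a of red blood cells rose 2.26-fold and 2.22-fold.

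Of 354 miRNAs tested with edgeR, 108 were called, 68 higher and 40 lower in TAC, and 157 had an unadjusted p under 0.05. The groups did not overlap for 107 of the 108, and for 182 of all 354 miRNAs, where chance gives 10%. The median called change was 1.55-fold for higher miRNAs (1.21 to 18.1) and 1.72-fold for lower ones (1.28 to 4.50). The balance of directions depended on the scaling: against 68 higher and 40 lower with TMM there were 50 and 56 with RLE size factors, 41 and 63 with upper quartile factors, 35 and 82 with totals without the 5 most abundant miRNAs, and 25 and 102 with library totals. DESeq2, which also changes the test, gave 58 and 53. Without a low-count filter there were 42 and 65, and with counts divided by places 51 and 52. The median of all log2 fold changes was 0.07 with TMM, -0.24 with library totals, -0.14 without the 5 most abundant miRNAs and -0.08 with upper quartile factors. Without a filter it was -0.14, over 1100 miRNAs. Changes below are relative to the TMM level. Leaving out TAC 81 gave 64 calls (18 of them lower) and leaving out TAC 78 gave 69 (44 higher, 25 lower), while 25, 26 and 25 were lower without sham 47, sham 68 and sham 69.

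**Figure D1:**
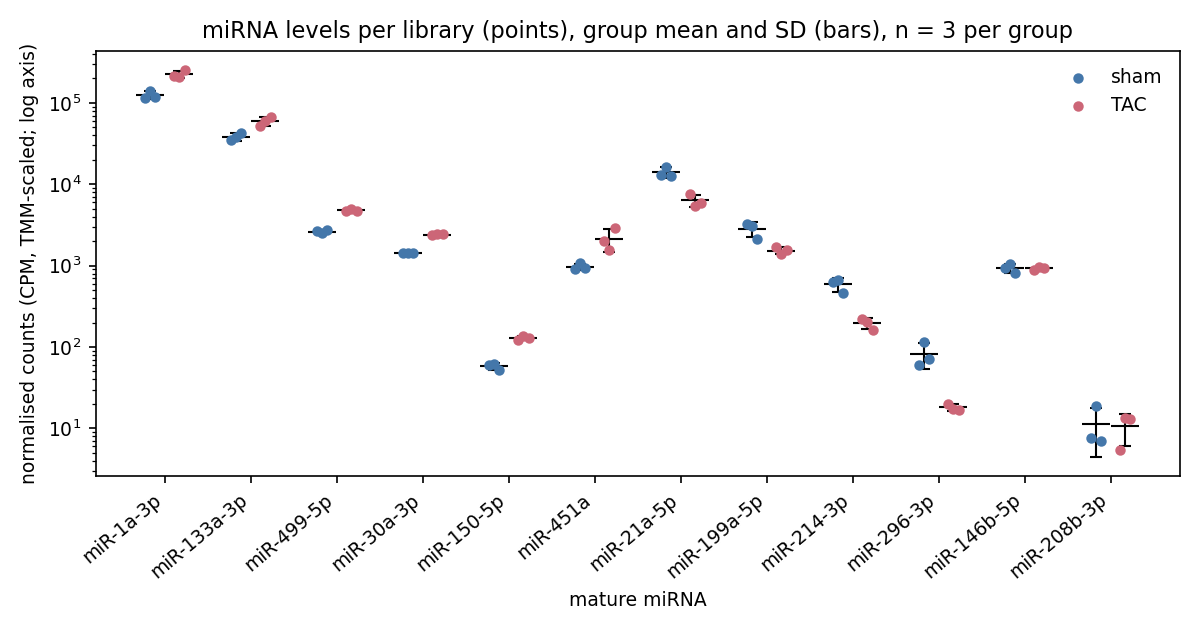
Normalised counts (CPM, log axis) of 12 miRNAs in each of the 6 libraries, with points for single mice and bars for the mean and SD of 3 mice per group. miR-499-5p, miR-150-5p and miR-451a lie higher in TAC and miR-21a-5p, miR-214-3p and miR-296-3p lower, with no overlap of the groups, while miR-146b-5p and miR-208b-3p overlap.

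Of the 10 tested muscle miRNAs, 8 rose, 0 fell and 2 did not pass, and the count adjusted over the list alone was also 8. miR-499-5p (TTAAGACTTGCAGTGATGTTT, chromosome 2, 155622893 to 155622913, in an intron of Myh7b) rose by 0.88 ± 0.08 on the log2 scale (edgeR adjusted p = 0.00044). miR-133a-3p rose by 0.62 ± 0.13 and miR-1a-3p by 0.86 ± 0.14, both with 2 places, on chromosomes 18 and 2, of which 1 place of miR-1a-3p overlaps the opposite-strand row of miR-1b-5p. miR-208a-3p, in an intron of the adult cardiac myosin gene Myh6, rose by 0.56 ± 0.13, whereas miR-208b-3p, in an intron of the fetal myosin gene Myh7, was at 11.3 ± 6.77 CPM in sham and 10.7 ± 4.54 in TAC (log2 fold change -0.05 ± 0.49). The list test gave a camera adjusted p = 0.00588, and adjusted p = 0.305 with an estimated correlation. With 1 row per near-identical group 7 of 9 members rose. With library totals 3 members were higher and 1 lower, and miR-133a-3p and miR-208a-3p lost their calls (adjusted p = 0.078 and 0.181). With a GC trend taken from each library, miR-1a-3p, of 27.3% GC, was not called, at a log2 change of 0.31 (adjusted p = 0.0756), and neither was miR-208a-3p, at 0.23 (0.231), which also lost its call without the 5 most abundant miRNAs and without a low-count filter.

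All 8 called members of the miR-30 family, an abundant family of cardiomyocytes, rose, and the other 2 of 10 tested did not pass (8 rose adjusted over the list alone). miR-30a-3p (chromosome 1, 23272315 to 23272336, intergenic) rose by 0.76 ± 0.08, miR-30e-5p, in an intron of Nfyc, by 0.84 ± 0.10 and miR-30b-5p by 0.75 ± 0.10. These 3 kept their calls under every alternative that tested them. The camera adjusted p was 0.000122, and adjusted p = 0.206 with an estimated correlation. miR-30a-5p, miR-30d-5p and miR-30e-5p are near-identical in sequence, but whether they share reads was not checked. With 1 row per near-identical group 5 of 7 members rose.

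Of the miRNAs commonly described as lowered in overloaded or failing hearts, 13 of 19 tested rose in TAC, 0 fell and 6 did not pass (14 rose adjusted over the list alone). Among them were miR-150-5p (1.17 ± 0.15), miR-101a-3p (0.76 ± 0.09), miR-29b-3p (0.62 ± 0.18) and the miR-30 and muscle miRNAs above. The camera adjusted p was 1.88e-05, and adjusted p = 0.206 with an estimated correlation. Library totals left 8 of the 13 higher calls, and 1 row per group of near-identical sequences left 7 of 12.

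Of the miRNAs commonly described as raised in such hearts, 6 of 23 tested fell, 1 rose and 16 did not pass, with the same counts adjusted over the list alone. miR-21a-5p (TAGCTTATCAGACTGATGTTGA, chromosome 11, 86584120 to 86584141, in an exon of Vmp1) fell by 1.15 ± 0.15 on the log2 scale (edgeR adjusted p = 0.000901), while its other arm miR-21a-3p was at 0.29 ± 0.47. miR-34c-5p (-1.26 ± 0.25), miR-214-3p (-1.58 ± 0.18), miR-214-5p (-1.19 ± 0.19) and miR-199a-5p (-0.89 ± 0.16) fell too. miR-328-3p, named after its values were seen, rose by 0.31 ± 0.10 (edgeR adjusted p = 0.0499), was at -0.00 with library totals, was not called with the other scalings and was called with the GC trend (0.49, adjusted p = 0.0049). miR-146b-5p (-0.00 ± 0.12), miR-34a-5p (-0.16 ± 0.21), miR-132-3p (-0.23 ± 0.19) and miR-195a-5p (-0.11 ± 0.18) did not pass. The list was lower than other miRNAs (camera adjusted p = 0.000787, adjusted p = 0.206 with an estimated correlation). It had 10 members lower with RLE size factors and 14 with library totals.

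The miR-199 and miR-214 miRNAs, made largely from the Dnm3os transcript in mesenchymal cells, fell in 5 of 6 tested members, and 1 did not pass (6 fell adjusted over the list alone). miR-214-3p (ACAGCAGGCACAGACAGGCAGT, chromosome 1, 162223438 to 162223459, in an exon of Dnm3os) and miR-199a-5p kept their calls under every alternative. The camera adjusted p was 0.00105, and adjusted p = 0.305 with an estimated correlation. Leaving out sham 47, sham 68, TAC 29, TAC 78 or TAC 81 left 3 members lower. The call lost was that of miR-199b-3p (-0.53 ± 0.16), together with miR-199a-3p, which has the same sequence and shares its reads and is named after its values were seen.

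The imprinted Dlk1-Dio3 cluster on chromosome 12, which is high in fetal tissue, had 10 of 27 tested members lower, 0 higher and 17 not passing, with 13 lower adjusted over the list alone. miR-668-3p, in an intron of Mirg, fell by 1.40 ± 0.24 on the log2 scale, miR-433-3p by 0.91 ± 0.24 and miR-127-3p by 0.66 ± 0.17. The median of the list was -0.55, and camera gave an adjusted p = 1.41e-07, with adjusted p = 0.288 with an estimated correlation. The list's share of counts was 0.451% ± 0.0719 in sham and 0.243% ± 0.0439 in TAC (SD, n = 3 each, exact permutation p = 0.1). Most single calls depended on which mice were kept, although that of miR-668-3p held in every alternative: 7 members were lower without sham 47, 4 without sham 68, 3 without sham 69, 6 without TAC 29, 5 without TAC 78 and 1 without TAC 81, while camera called the list in each of these fits, and library totals gave 22 lower.

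miR-296-3p (GAGGGTTGGGTGGAGGCTCTCC, chromosome 2, 174267058 to 174267079) was at 82.6 ± 29.0 CPM in sham and 18.1 ± 1.62 in TAC, and miR-298-5p (chromosome 2, 174267553 to 174267575, same strand) at 51.1 ± 12.7 and 11.3 ± 1.26. Both lie outside annotated host genes. Their log2 changes of -2.17 ± 0.27 and -2.15 ± 0.25 stayed called under every alternative. The other arm of the first hairpin, miR-296-5p, named after its values were seen, was at -0.43 and did not pass. miR-455-3p, in an intron of the collagen gene Col27a1, fell by 0.93 ± 0.16. miR-210-3p of the hypoxia list, induced by HIF1, fell by 0.73 ± 0.17. That list and the miR-34 family, with miR-34c-5p lower, had 2 tested members each and were not tested as lists.

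**Figure D2:**
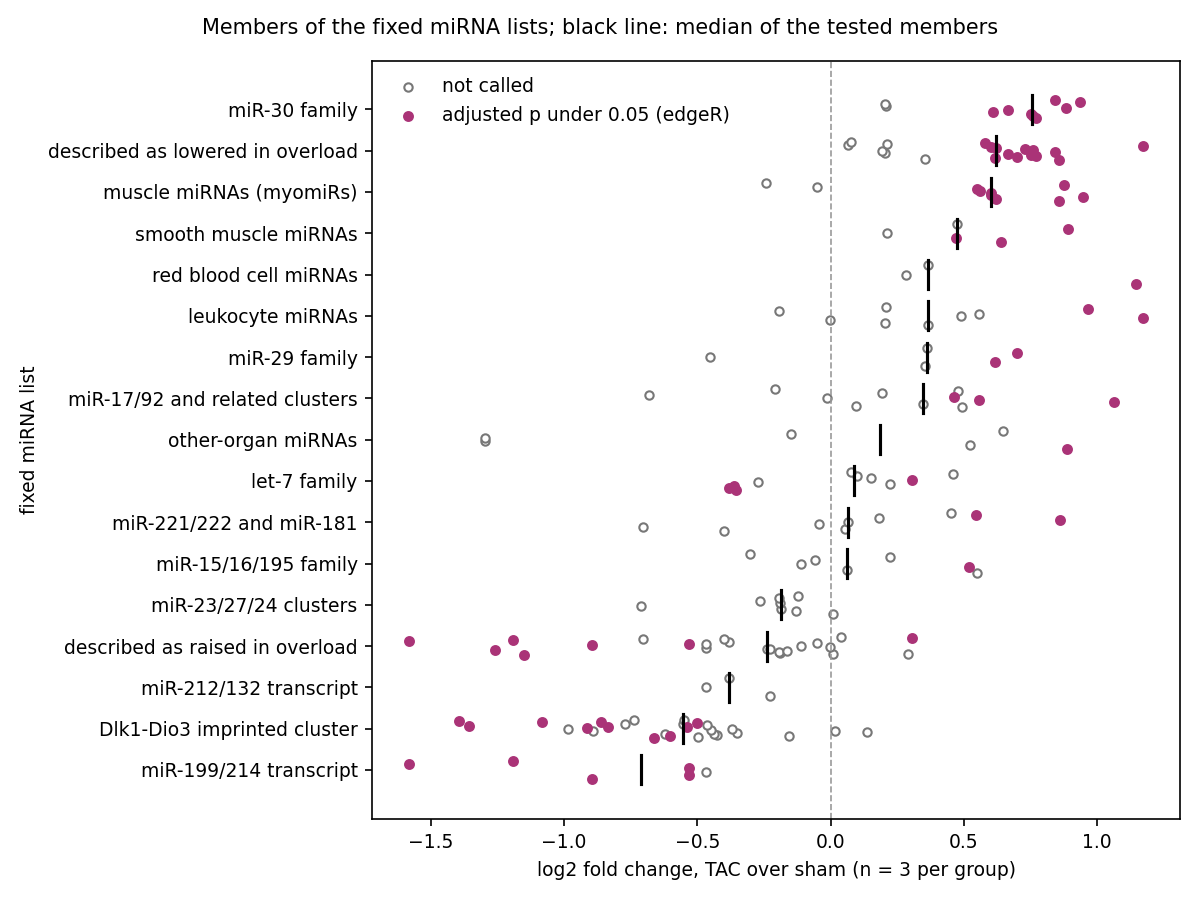
Log2 fold change of TAC over sham for each tested member of the 17 tested lists, 1 point per miRNA, filled where the edgeR adjusted p was under 0.05, with a line at each list's median. Medians run from -0.71 in the list of miR-199 and miR-214 to 0.76 in the miR-30 family, at the TMM scaling. The let-7 median of 0.09 is below 0 with library totals and with the GC trend. So are those of the lists with miR-15 and with miR-221, from 0.06 and 0.07. The red blood cell median is below 0 with the GC trend, and that of other organs with library totals.

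Among markers of other cells, 3 of 5 smooth muscle miRNAs rose and 2 did not pass (3 rose adjusted over the list alone): miR-143-3p by 0.64 ± 0.11, miR-145a-3p by 0.89 ± 0.13 and miR-143-5p by 0.47 ± 0.12, the last losing its call in 8 of 20 alternatives. Their camera adjusted p = 0.0316 became adjusted p = 0.305 with an estimated correlation, and 0.0641, 0.0743, 0.0536 and 0.0547 without sham 68, sham 69, TAC 29 and TAC 81. Of 9 leukocyte miRNAs tested, 2 rose (1 adjusted over the list alone) and 7 did not pass: miR-150-5p rose by 1.17 ± 0.15 and miR-223-5p by 0.97 ± 0.31, whereas miR-223-3p was at -0.19 ± 0.24 and miR-155-5p at 0.56 ± 0.19 (edgeR adjusted p = 0.0523). The call of miR-223-5p was lost in 15 of the 17 alternatives that tested it. The list was not called by camera (adjusted p = 0.079, against 0.00794 by fry), except without sham 47 (0.0443) and with 1 row per near-identical group (0.0365). Of 3 red blood cell miRNAs, miR-451a rose by 1.15 ± 0.20 (also adjusted over the list alone) and 2 did not pass (camera adjusted p = 0.271). The red blood cell share of counts was 0.119% ± 0.00807 in sham and 0.204% ± 0.0588 in TAC (SD, n = 3 each, exact permutation p = 0.1). Of 6 tested miRNAs typical of other organs, miR-192-5p rose by 0.89 ± 0.11 and 5 did not pass, with 2 higher adjusted over the list alone (camera adjusted p = 0.685, with a mean of -0.11 and a median of 0.19 that turned to -0.14 without sham 47, -0.11 without TAC 29 and -0.12 with library totals and was 0.53 without sham 68 and 0.54 without sham 69). Only 1 endothelial miRNA, miR-126b-3p, could be tested, and it did not pass, but it too lies over a row on the opposite strand, so its count says little about endothelial cells. miR-126a-3p, miR-142a-3p, miR-486a-5p and miR-122-5p were at 0 in every library, and each lies over a row on the opposite strand, so these zeros do not measure absence.

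The let-7 family, widely expressed in differentiated cells, split: let-7a-5p (-0.36 ± 0.11), let-7b-5p (-0.38 ± 0.11) and let-7c-5p (-0.36 ± 0.11) fell, let-7f-5p rose by 0.30 ± 0.09, a rise that turned to -0.00 with library totals and -0.13 with the GC trend and lost its call in 17 of 19 alternatives, and 6 of 10 did not pass (the same adjusted over the list alone). The family held 20.2% ± 1.85 of counts in sham and 14.3% ± 0.341 in TAC (SD, n = 3 each, exact permutation p = 0.1). These shares are of total counts, not at the TMM level, and count some reads more than once, as let-7a-5p, let-7c-5p and let-7f-5p have 2 places each. The let-7 list was not called (camera adjusted p = 0.719, direction down against a median of 0.09). With the GC trend camera called it lower (adjusted p = 0.017). With 1 row per near-identical group the list was not tested. The 3 falling rows are near-identical to each other in sequence and can share reads, so they are not independent measurements. The 3 falls lost their calls without sham 69, TAC 29, TAC 78 or TAC 81, and without sham 47. Of 5 miR-29 members, which target collagen mRNAs, miR-29b-3p and miR-29c-3p rose by 0.62 ± 0.18 and 0.70 ± 0.23 (2 adjusted over the list alone), and 3 did not pass, among them miR-29a-3p at 0.35 ± 0.14 (list camera adjusted p = 0.344). The call of miR-29b-3p was lost in 11 of 20 alternatives and that of miR-29c-3p in 14 of 19, both without sham 68, sham 69, TAC 29 or TAC 78.

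In the remaining lists 1 of 7 members of the family of miR-15, miR-16 and miR-195 rose (miR-16-5p, 0.52 ± 0.12; camera adjusted p = 0.719), 3 of 11 miR-17 and miR-92 cluster members rose (miR-19b-3p, 1.07 ± 0.21, miR-25-3p and miR-20a-5p; 0.271) and 2 of 9 members of the list of miR-221, miR-222 and miR-181 rose (miR-181c-5p and miR-181a-1-3p; 0.684). Adjusted over the list alone, 1, 4 and 2 members rose. miR-20a-5p lost its call in 14 of 20 alternatives, miR-181a-1-3p in 13 of 19, miR-16-5p in 5 of 20, among them those without TAC 29 and without TAC 81, and miR-25-3p and miR-181c-5p in 4 of 20 each, the latter without sham 69, TAC 78 and TAC 81. With library totals the family of miR-15, miR-16 and miR-195 had 0 members higher and 1 lower. In that setting 1 member of the miR-17 and miR-92 clusters was higher and 3 lower, and of the list with miR-181 0 were higher and 3 lower. That list had 0 calls without sham 69, TAC 78 or TAC 81, 2 higher and 2 lower without TAC 29, and 1 and 1 with RLE size factors. The 8 tested members of the miR-23, miR-27 and miR-24 clusters and the 3 tested members of the miR-212 and miR-132 transcript gave 0 calls by edgeR, also adjusted over the list alone, with camera adjusted p = 0.176 and 0.184, and 3 and 2 were lower with library totals. fry, which asks whether members move one way on balance, gave 0.0163 and 0.0399 for them, with medians of -0.19 and -0.38.

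The largest rises came from 3 rows whose sham counts were highest in sham 69. miR-6343 (chromosome 1, 76509620 to 76509641, in an intron of the noncoding gene Gm29069) had 0, 3 and 33 counts in sham 47, 68 and 69 and 127, 139 and 82 in TAC 29, 78 and 81. miR-6538, in an intron of Rnf144a, was at 33.9 ± 31.4 CPM in sham and 422 ± 113 in TAC. miR-7225-5p, within an exon of Pde4dip on its own strand, was at 5.89 ± 5.31 and 49.8 ± 5.65 CPM. Their log2 changes were 4.18 ± 0.78, 3.64 ± 0.56 and 3.18 ± 0.56, called under every alternative, but the sizes rest on sham 69, without which they were 7.12, 4.74 and 4.26, against 3.45, 3.29 and 2.53 without sham 47. Reads of the host transcripts cannot be told from miRNA reads in such rows.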

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

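The GC trend, the near-identical grouping, the division by places, the thinning and the removal of overlapping rows were chosen after the data were seen. All calls shared with any alternative kept their direction, and 30 of the 55 named and called miRNAs stayed called in every one of the 20 alternatives that tested them, miR-499-5p, miR-30a-3p, miR-150-5p, miR-21a-5p, miR-214-3p, miR-296-3p and miR-298-5p among them. The total of 108 lay between 64 and 127 over all alternatives. The split moved with scaling and filter: 25 higher and 102 lower with library totals, 41 and 63 with upper quartile factors, 35 and 82 without the 5 most abundant miRNAs, and 42 and 65 without a filter. Each of these lowers the common level (median log2 fold change -0.24, -0.08, -0.14 and -0.14, against 0.07 with TMM). Leaving out 1 mouse gave 64 to 83 calls, 44 to 57 higher and 18 to 29 lower, with fewer samples in each fit. let-7f-5p reversed to -0.0036 with library totals and to -0.13 with the GC trend, and the let-7 median to -0.27 with the GC trend; the cause was not tested. The GC trend left 86 calls, 56 higher and 30 lower, 75 of them shared with the uncorrected fit. The 7 lists called by camera fell to 0 with an estimated correlation, and fry called them with adjusted p from 0.00116 to 0.0188. The difference in the share of miR-1a-3p was 4.22 percentage points with counts divided by places, that is by 2 for that row. As 1 of its 2 places overlaps an opposite-strand row, whose reads may be uncounted, the division may be wrong, and without overlapping rows it is not tested. Thinning every library to the smallest total gave 95 calls, 86 of them shared, with 17 lost and 5 not tested. No paired analysis was possible because the groups share no animal numbers.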

Other observations

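All tests here were chosen after the results were seen. Outside the fixed lists, both arms of several hairpins moved together, named after their values were seen except for miR-455-3p: miR-378a-5p and miR-378a-3p rose by 0.68 ± 0.12 and 0.55 ± 0.10, miR-185-5p and miR-185-3p by 0.52 ± 0.11 and 0.80 ± 0.16, while miR-455-5p and miR-455-3p were at -0.70 ± 0.17 and -0.93 ± 0.16. Arms were paired only where the names differ in the arm alone, so rows with a numbered 3p name, such as let-7a-1-3p, were left out. Across the 88 hairpins so paired, the log2 changes of the arms correlated with a Pearson r of 0.546 and a Spearman rho of 0.577 (permutation p = 2e-05 for each, the smallest these permutations give, and the same after adjustment over the 2 correlations computed). Pearson r was 0.542 without the 2 farthest hairpins. The correlation is across genes, which are not independent replicates. The arms had the same sign in 62 of these 88 hairpins, and in 13 of 13 with both arms called, but not in others such as miR-21a (-1.15 for the 5p arm, 0.29 for the 3p arm), miR-25 (-0.68 and 0.46) and miR-223 (0.97 and -0.19). Among the rows left out, let-7a-1-3p (0.46) and let-7c-2-3p (0.45), named after their values were seen, were called higher. Their 5p rows let-7a-5p and let-7c-5p, with 2 places each, were called lower (-0.36 each). miR-30c-1-3p and miR-30c-5p were both called higher (0.88 and 0.665). A candidate explanation for part of these changes is the supply of the hairpin. For let-7 the mean log2 CPM of the 3p arms minus that of the 5p arms was -6.82 ± 0.03 in sham and -6.62 ± 0.17 in TAC (SD, n = 3 each), a difference within 2 times the summed SDs. The single calls went apart, however. Of 8 tested 3p arms 3 were higher and 0 lower (median log2 change 0.31), and of 8 tested 5p arms 1 was higher and 3 lower (-0.09). The averaged contrast therefore does not show that the let-7 arms moved together.

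The directions in TAC ran against the usual description of pressure overload: 19 of 20 called members of the lists of miRNAs described as raised or lowered moved the other way. Library scaling is argued against, since the mean log2 CPM of the lowered list minus that of the raised list, which no library factor can move, was 2.38 ± 0.07 in sham and 3.35 ± 0.02 in TAC (SD, n = 3 each), a difference of 0.97. GC content of the mature sequence took part of it but not the whole: log2 changes fell with GC content across 353 miRNAs (Spearman rho -0.281, permutation p = 2e-05, the same after adjustment; Pearson r -0.105, permutation p = 0.0481, and -0.243 without the 2 farthest), and after a quadratic GC trend fitted on miRNAs outside both lists the difference was 0.78, with SDs of 0.09 and 0.02. A larger share of heart muscle cells in the TAC samples, acting alone, would lower the markers of other cells alike. The smooth muscle list minus the list of miR-199 and miR-214 instead rose by 1.40, from -0.99 ± 0.28 to 0.40 ± 0.09. Both lists had been seen to move apart before this contrast was chosen. It cannot decide on a larger muscle share combined with a change in other cells. Exchanged group labels and a true response of these hearts at this stage cannot be told apart. The 19 of 20 is the pattern itself and no separate value here decides. Several of the 20 rows are near-identical and may share reads. The lower members of the raised list other than miR-21a-5p and miR-34c-5p are the miR-199a and miR-214 rows, which are also in the list of miR-199 and miR-214 (estimated correlation 0.83). The 20 are therefore not separate pieces of evidence. miR-208b-3p, miR-146b-5p, miR-34a-5p and miR-132-3p gave no call in either direction.

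miRNAs known to be abundant in vessels, blood or heart, such as miR-126a-3p, miR-142a-3p, miR-486a-5p and miR-24-3p, were at 0 in every library. A hairpin not made in these hearts is argued against for 3 zero rows only, whose other arm, free of overlap, was counted: miR-142a-3p (miR-142a-5p had 1470 counts), miR-30e-3p (58772) and miR-497a-3p (890). It was not tested for miR-126a, miR-486a and miR-24. Of 90 rows overlapped at every place by a row on the opposite strand, 82 were at 0. That was 91.1% against 41.9% of rows with no overlap (Fisher's exact p = 1.1e-21). Many of these rows overlap each other in pairs, which the test treats as independent, so its p overstates the evidence. They also include miRNAs typical of other organs, such as miR-122-5p and miR-9-5p, which may be at 0 for that reason. The excess of zeros is what a count without strand would give, by leaving reads over opposite-strand rows uncounted. miR-3074-1-3p, with 1910 counts, is an exception, and its partner miR-24-1-5p was at 0.

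The 6 mice can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 108 miRNAs by edgeR and the other splits at most 0, and 1 of the 10 splits reached the real value. Every other split puts sham and TAC mice in both groups, which adds the difference between them to the spread. The 0 calls of those splits are therefore not a level for groups that do not differ.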
